A study of Mus musculus with 9 samples.

How the data were processed

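Small RNA libraries from 9 samples were used, 3 per group, 8 of them with the cell line label RAW264.7 and 1 with RAW264.8. Per the labels' protocols, about 5 µg of total RNA went into TruSeq Small RNA libraries, which were sequenced on a HiSeq instrument, and the authors filtered reads with the ACGT101-miR program to remove adapter dimers, junk, low-complexity reads, other RNA families and repeats. The deposited signal values are read counts per miRNA sequence scaled per library by the authors, headed as normalized counts. The normalization formula, the miRBase release, the mapping settings and the genome build are not given in the sources used here. The filter against tRNA and other families can lower sequences that resemble them, and the scaling fixes library sums near each other, so a change shared by most miRNAs would not be seen.

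The table had 1608 rows, of which 37 repeated the sequence of another row with the same values, leaving 1571 sequences. A further 23 tested sequences were numbered copies of a name with equal values in all libraries and were kept. Sequences were searched in 1174 mouse miRNA hairpins of GENCODE vM21 (GRCm38), where 674 were found whole, 168 by their core and 729 not at all. Coordinates are given for those with a single place. The values were not whole reads: only 85.2 to 90.3% of low values per library lay within 0.01 of a whole multiple of the step taken as 1 read, so depth is an estimate and tests made for read numbers were not run. The test planned for normalized values was used instead.

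Each comparison used limma 3.58.1 in R 4.3.3 on log2(value + 1), for sequences with a mean of at least 1 in some group (1561), with 1 mean per group over all 9 libraries, a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Log2 differences on this scale understate changes of low sequences. A sequence without any residual variance was left out of a fit, a step added after seeing the data. It removed 0 from the main result and 86 where 1 library was left at 10 µM. It was added because a first run of that setting had called many sequences without residual variance. Lists of miRNAs, 20 in all, were fixed before the data were examined and tested with camera (preset correlation 0.01, then estimated) and fry. Camera sets list members against all other sequences tested, so a list that rose or fell in it did so relative to them. Members were matched through the mouse hairpin and arm or the name without its species prefix, since the table names many conserved miRNAs after other species. That match replaced the planned one by mouse name after the table was seen.

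Named miRNAs follow a rule fixed beforehand. It takes up to 10 rises and 10 falls that pass with no overlap and a mean of at least 50, and where under 10 pass, all of them and the 5 smallest p values as not passing. It adds 10 macrophage miRNAs, the 5 most abundant sequences and up to 4 members per list. On simulated data with each sequence's own spread and 200 abundant sequences changed, limma recovered 70 of 100 changed by 2-fold and 96 of 100 by 4-fold for 10 µM against control, 65 and 92 for 1 µM against control, and 71 and 98 for 10 against 1 µM. These runs also called 10, 8 and 6 unchanged sequences, in that order. With fewer true changes than 200 the adjustment is stricter, so recovery could be lower. For abundant sequences the median half-width of the 95% interval was 0.53 on the log2 scale. Group shares were compared with an exact permutation test, two-sided, which for 3 against 3 cannot go below 0.10. Other pseudocounts, filters, scalings, feature sets, a replicate block and left-out libraries were tried as alternatives. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.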

Results

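Small RNAs were sequenced from RAW264.7 cells, a mouse macrophage-like line. Per the labels, cells had lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages, for 6 h and then ginsenoside Rd (GRd), a saponin from ginseng, for 24 h. There were 9 libraries in 3 groups of 3: control, GRd at 1 µM and GRd at 10 µM. The treatment label of the control group says that it had no LPS and no GRd, while its description and the treatment protocol place it at 0 µM GRd after LPS. This conflict was not resolved, so each comparison with control covers either GRd alone or LPS and GRd together. The comparison of 10 with 1 µM differs by the labels in dose and in 1 cell line label. Library 3 of the 10 µM group has the cell line label RAW264.8, although its title names RAW264.7 as for the other 8. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

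The deposited values, normalized counts per miRNA sequence, summed to between 6235670 and 6815350 per library after repeated sequences were counted once. Steps between low values gave an estimated 4933690 to 9214210 reads behind these sums. Sequences found in mouse miRNA hairpins took 97.5 to 98.7% of each library. The 5 with the highest means over the 9 libraries were miR-99b-5p (556471 ± 65564 normalized counts in control, SD, n = 3), miR-221-3p (469598 ± 15238), miR-92a-3p (368069 ± 61362), miR-222-3p (401538 ± 38660) and miR-5099-3p (273458 ± 43329). miR-5099-3p stood at 1058760 in library 3 of the 10 µM group, and in control it lay below miR-21a-5p (299121 ± 31611). Over the 414 sequences with a mean of at least 50, 7 libraries correlated with each other at a median r of 0.992 across sequences, which are not independent replicates. Library 3 of the 10 µM group had a median r of 0.927 with the other 8 and library 2 of that group 0.974. The median SD on the log2 scale was 0.17 in control, 0.13 at 1 µM and 0.46 at 10 µM, where libraries 1 and 2 alone gave 0.20.

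**Figure D1:**
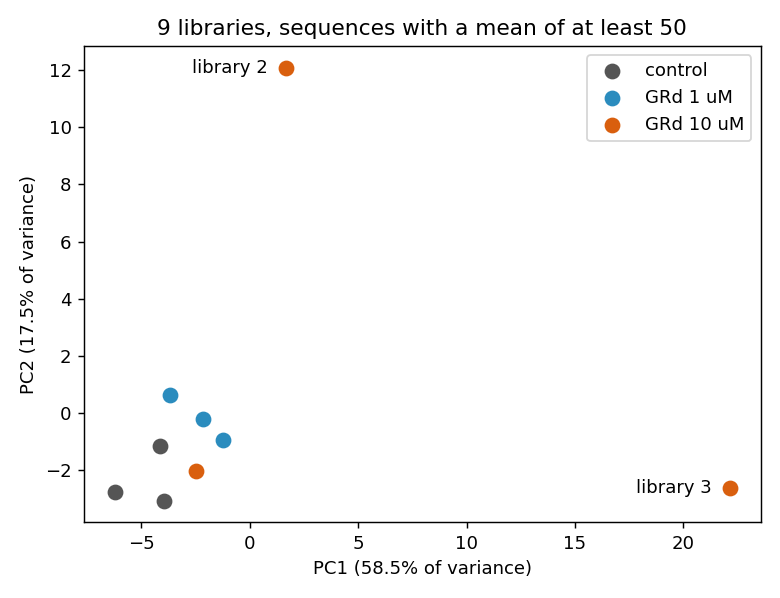
Principal components of the 9 libraries over sequences with a mean of at least 50, with component 1 on the x axis (58.5% of variance) and component 2 on the y axis (17.5%). Each point is a library, coloured by group, and libraries 3 and 2 of the 10 µM group lie apart at 22.1 on component 1 and 12.1 on component 2.

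The first comparison asked which miRNAs differed at 10 µM GRd. Differences are given on the log2(value + 1) scale. miR-155-5p, an LPS-induced miRNA of activated macrophages (chromosome 16, 84714143 to 84714165, GRCm38, in Mir155hg), stood at 57580 ± 24948 normalized counts at 10 µM and 64100 ± 8867 in control (SD, n = 3 each), a log2 difference of -0.24 (SE 0.27). miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling (chromosome 11, 43374435 to 43374456), stood at 129870 ± 65562 and 167565 ± 17145, a log2 difference of -0.54 (SE 0.33). Its 3 values at 10 µM were 168935, 166496 and 54178, the lowest in library 3. miR-21a-5p (log2 difference -0.09), miR-223-3p (0.07), miR-125b-5p (0.13), miR-132-3p (0.17), miR-222-3p (-0.32), miR-27a-3p (-0.24), let-7c-5p (-0.21) and miR-147-3p (-0.05) did not pass the test either. Of 1561 sequences, 0 passed limma with Benjamini-Hochberg adjusted p under 0.05, 86 had an unadjusted p under 0.05 where 78.05 would by chance, and the smallest adjusted p was 0.224.

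The smallest p belonged to miR-214-3p (chromosome 1, 162223438 to 162223459, in Dnm3os), a miRNA of mesenchymal cells, with 39.0, 48.2 and 2654 normalized counts at 10 µM and 11.7, 0 and 0 in control (limma adjusted p = 0.224 by Benjamini-Hochberg, not past the threshold). miR-145a-5p, typical of smooth muscle (chromosome 18, 61647866 to 61647888), followed with 13.9, 13.3 and 853 at 10 µM and 0, 3.43 and 0 in control. Next came 3 sequences found in no mouse hairpin, efu-mir-9277-p3_1ss8CT (log2 difference -1.40), bta-miR-2478_L-2 (0.64) and hsa-miR-1260a (0.93), none past the threshold. Among 414 abundant sequences, 40 had no overlap between the groups (9.66%, where chance gives 10%). The count without library 1 of the 10 µM group was 13 (7 of them forms of miR-1246, miR-1290, miR-1307-5p or miR-589, such as hsa-miR-1246_L-1R+2 at 17.1, 2394 and 376; miR-148a-3p and miR-214-3p were others), and without library 3 it was 1, PC-5p-3713_1568 at a log2 difference of -0.74. Apart from miR-214-3p, these were chosen after their values were seen.

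Of 18 miRNA lists with a set test, 4 passed camera with a preset correlation at 10 µM against control. The list of liver, serum and red cell miRNAs rose (6 of 6 members higher, median log2 difference 1.72, camera adjusted p = 0.00138, adjusted p = 0.630 with an estimated correlation), with miR-451a, abundant in red cells, at 36.2, 83.0 and 201 and 13.8, 26.8 and 22.5 in control, and the liver miRNA miR-122-5p at 77.4, 82.0 and 456 and 47.8, 85.1 and 34.5. The fibroblast and muscle list rose (6 of 7 members higher, median log2 difference 1.25, camera adjusted p = 0.00390, adjusted p = 0.678 with an estimated correlation), with miR-143-3p at 13.2, 16.4 and 647 and miR-199a-5p at 285, 289.6 and 1333, high in library 3. The myeloid and haematopoietic list fell (15 of 20 members lower, median log2 difference -0.25, camera adjusted p = 0.00984, adjusted p = 0.678 with an estimated correlation), with miR-181a-5p at a log2 difference of -0.40 and miR-142a-3p at 0.30. The p53-regulated miR-34 list rose (5 of 5 members higher, median log2 difference 1.04, camera adjusted p = 0.0495, adjusted p = 0.630 with an estimated correlation), with miR-34b-3p at 39.7, 44.1 and 182, against a mean of 20.2 ± 4.75 in control. The log2 differences of its members ranged from 0.02 for miR-34a-5p to 1.84 for miR-34c-3p. Means were low for miR-34c-3p (24.1 at 10 µM and 10.5 in control) and miR-34a-3p (24.3 and 11.3). No list passed with an estimated correlation. Without library 3 of the 10 µM group the preset adjusted p was 0.129 (median 1.00) for the liver list, 0.574 (median -0.04) for the fibroblast list, 0.325 (median -0.06) for the myeloid list and 0.129 (median 1.04) for the miR-34 list, whose median thus stayed, and without libraries 2 and 3 the myeloid list turned upward in the test (adjusted p = 0.912). The miR-34 call was also lost without control library 3, at 0.293 (median 0.51), without 10 µM library 1, at 0.157 (median 0.78), and without 1 µM library 3, at 0.0521 (median 1.04), and the myeloid call without control library 1, at 0.0891 (median -0.21). Summed to mature miRNAs the adjusted p was 0.209 (median -0.11) for the myeloid and 0.0635 (median 1.04) for the miR-34 list. With equal-valued copies counted once, as the 2 mdo-miR-181a-5p copies in the myeloid list, both had an adjusted p of 0.0623 (medians -0.23 and 1.04). The miR-34 call was also lost with pseudocount 0.1, at 0.0522 (median 1.11), with pseudocount 10, at 0.0539 (median 0.67), and with the GC trend removed, at 0.0527 (median 1.04), the myeloid call with a mean of at least 50, at 0.117 (median -0.23), and all 4 calls with array weights, at 0.156 (median 1.23) for the liver, 0.294 (median 0.19) for the fibroblast, 0.156 (median -0.12) for the myeloid and 0.294 for the miR-34 list. Without libraries 2 and 3 of the 10 µM group, which leaves a lone library, the median was 0.68 for the liver, 0.06 for the fibroblast and 0.97 for the miR-34 list. Adjusted over the list alone, 2 liver, 2 fibroblast, 1 miR-34 and 0 myeloid members passed limma, and 0 passed over all sequences. The other 14 lists did not pass, among them the LPS-induced (median -0.05, adjusted p = 0.2198), miR-15/16 (13 of 14 lower, adjusted p = 0.0731), let-7 (adjusted p = 0.433) and Dlk1-Dio3 lists (median 0.72, adjusted p = 0.335). The anti-inflammatory list (14 of 25 lower, median -0.02) had a camera adjusted p of 0.0731, and 0.678 with an estimated correlation. It passed camera downward with equal library totals, at 0.0453 (median -0.06), and with median-of-ratios scaling, at 0.0466 (median -0.04). It also did without control library 3, at 0.02325 (median -0.13), and without 10 µM library 1, at 0.0225 (median -0.22). With repeated sequences kept it passed at 0.0290 (median -0.03). The Dlk1-Dio3 member miR-434-3p had a log2 difference of 0.72 from a value of 3.48 in library 1 of the 10 µM group and 0 in all others. Without library 1 of the 10 µM group camera passed the miR-15/16 and LPS-induced lists downward, at adjusted p of 0.00250 (median -0.62) and 0.0225 (median -0.24). The LPS-induced list also passed downward without library 2, at 0.04925 (median -0.11), and the miR-15/16 list without control library 3, at 0.02325 (median -0.31). With libraries 2 and 3 left out instead, their medians were above 0, at 0.25 (LPS-induced) and 0.44 (miR-15/16). The downward calls used the preset correlation. With all libraries and an estimated correlation the camera adjusted p was 0.776 for the LPS-induced and for the miR-15/16 list. With fry, which asks whether members move one way on balance, 0 lists passed in any comparison, and the smallest adjusted p was 0.177.

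**Figure D2:**
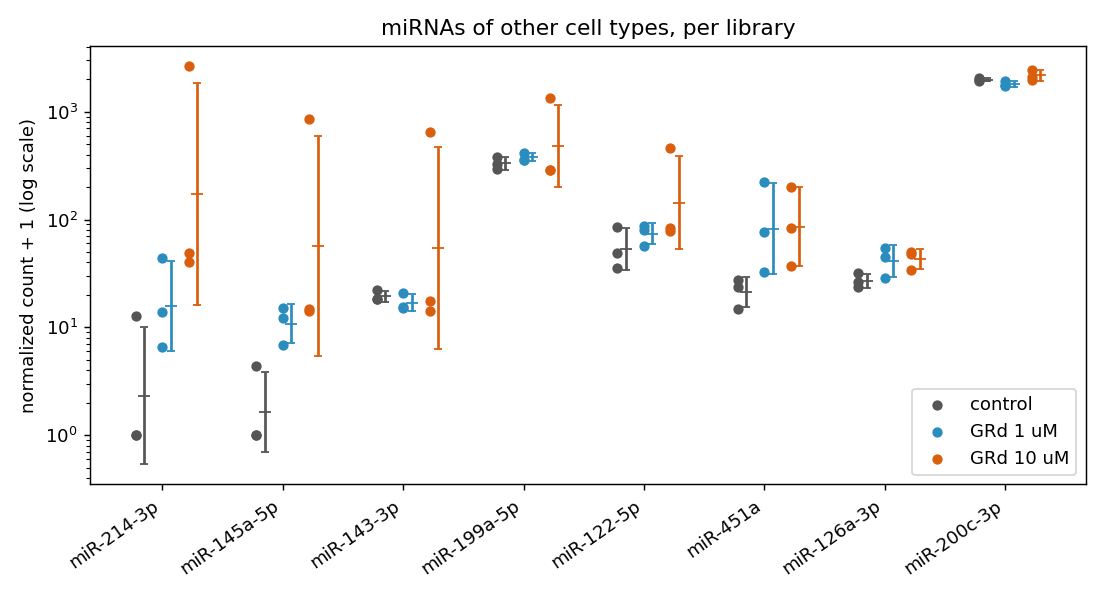
Normalized counts plus 1 on a log axis for miRNAs of other cell types, 3 libraries per group as points, with the mean and SD taken on the log scale as bars. miR-214-3p reached 2654 in library 3 of the 10 µM group and at most 48.2 in the other 8 libraries.

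The second comparison asked the same of 1 µM GRd. miR-155-5p stood at 64137 ± 12050 normalized counts and 64100 ± 8867 in control (SD, n = 3 each), a log2 difference of -0.01 (SE 0.27) with a 95% interval from -0.57 to 0.56. miR-146a-5p differed by 0.15, miR-21a-5p by 0.07, miR-223-3p by 0.10, miR-125b-5p by -0.11, miR-132-3p by 0.01, miR-222-3p by -0.05, miR-27a-3p by 0.06, let-7c-5p by -0.03 and miR-147-3p by 0.14, all on the log2 scale and none past the test. The smallest p values belonged to hsa-miR-7977_1ss6AG (log2 difference 0.58), miR-451a (1.95), miR-6916-5p (-2.73), pal-miR-9226-5p_L-4 (0.55) and miR-6958-3p (-3.40), none past the threshold. The largest of these differences rest on low values. In control miR-6916-5p stood at 5.31, 4.12 and 7.96 and miR-6958-3p at 8.49, 9.61 and 10.6, and both were listed at 0 in each 1 µM library. Of 1561 sequences, 0 passed limma with Benjamini-Hochberg adjusted p under 0.05 and 28 had an unadjusted p under 0.05, where 78.05 would by chance. Among the abundant sequences 56 had no overlap between the groups, 42 higher and 14 lower at 1 µM (13.5%, where chance gives 10%). The spread came from all 3 groups, and with only the 6 libraries compared 59 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0797.

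The list of 28 LPS-induced miRNAs had 22 members higher and 5 lower at 1 µM, with a median log2 difference of 0.04 (camera adjusted p = 0.432). The liver, serum and red cell list rose (6 of 6 higher, median 0.80, camera adjusted p = 9.88e-04), with miR-451a at 31.6, 76.0 and 223 and miR-144-3p, from the same transcript, at 0, 7.60 and 15.6. With an estimated correlation its adjusted p was 0.616, and without library 3 of the 1 µM group the preset value was 0.102 (median 0.82), so the median stayed. Without control library 3 it was 0.0206 (median 0.48). Adjusted over the list alone, 1 member passed limma. The other 17 lists did not pass.

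The third comparison, 10 against 1 µM, asked what the dose changed. miR-155-5p differed by -0.23 (SE 0.27) on the log2 scale, miR-146a-5p by -0.69 (SE 0.33), miR-21a-5p by -0.16, miR-223-3p by -0.03, miR-125b-5p by 0.24, miR-132-3p by 0.16, miR-222-3p by -0.26, miR-27a-3p by -0.29, let-7c-5p by -0.18 and miR-147-3p by -0.19, none past the test. miR-331-3p (chromosome 10, 93963783 to 93963803, in Vezt) had 1758, 1656 and 1143 normalized counts at 10 µM and 2465, 2355 and 2232 at 1 µM, without overlap (limma adjusted p = 0.683 by Benjamini-Hochberg, not past the threshold). The other small p values belonged to efu-mir-9277-p3_1ss8CT (-1.30) and to the predicted candidates PC-5p-47035_44 (-3.75), PC-3p-43748_50 (3.45) and PC-5p-64858_21 (3.61). Of 1561 sequences, 0 passed limma with Benjamini-Hochberg adjusted p under 0.05 and 75 had an unadjusted p under 0.05, where 78.05 would by chance. Among the abundant sequences 48 had no overlap (11.6%, where chance gives 10%). Without library 1 of the 10 µM group 9 passed, 6 of them forms of miR-1246, miR-1290, miR-1307-5p or miR-589.

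The myeloid list fell from 1 to 10 µM (15 of 20 members lower, median log2 difference -0.17, camera adjusted p = 0.0116), as did the LPS-induced list (20 of 28 lower, median -0.16, adjusted p = 0.0219), with miR-21a-3p at 2631, 2433 and 784 and 2906, 3177 and 2967, and miR-221-5p at 4229.9, 3736 and 2103 and 4011, 5439 and 5608. With an estimated correlation both had an adjusted p of 0.764. Without library 3 of the 10 µM group the preset adjusted p was 0.450 (median 0.03) for the myeloid and 0.894 (median 0.00232) for the LPS-induced list, without library 3 of the 1 µM group 0.573 (median -0.02) and 0.174 (median -0.10), and without libraries 2 and 3 both turned upward in the test (adjusted p = 0.969 and 0.454). The myeloid median was -0.37 without library 1 of the 1 µM group and -0.29 without library 1 of the 10 µM group, where the LPS-induced median was -0.25. Summed to mature miRNAs the adjusted p was 0.0544 (median -0.14) for the myeloid and 0.0544 (median -0.07) for the LPS-induced list. With the stricter filter both had an adjusted p of 0.0729 (medians -0.17 myeloid and -0.16 LPS-induced). With a mean of at least 50 both had 0.249 (medians -0.10 and -0.15), and with array weights 0.506 (median -0.01) and 0.876 (median -0.03). The fibroblast and muscle list did not pass (6 of 7 higher, median 1.25, adjusted p = 0.0672). It passed camera upward with only the 6 libraries compared, at 0.00794 (median 1.46), and with the replicate block, at 0.0401 (median 1.25). It also did without control library 2, at 0.0187 (median 1.46), and without 1 µM library 2, at 0.0304 (median 1.25). Without 10 µM library 1 or 2 it passed at 0.0210 and 0.0123 (median 1.87 each), and under the other alternatives it did not. Adjusted over the list alone, 0 members of these 3 lists passed limma.

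**Figure D3:**
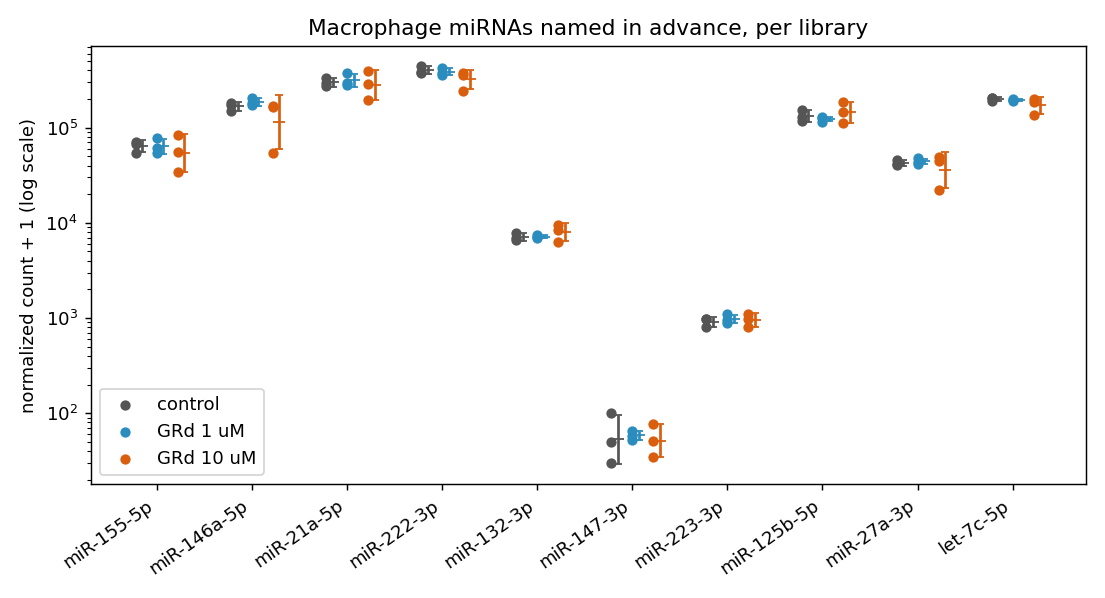
Normalized counts plus 1 on a log axis for 10 miRNAs named before the data were examined, 3 libraries per group as points, with the mean and SD taken on the log scale as bars. miR-146a-5p lay at 54178 in library 3 of the 10 µM group and at 148167 or more in the other 8 libraries.

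The responses to the 2 doses were then set against each other. The log2 differences from control had a covariance of 0.319 and a Pearson r of 0.458 across 1561 sequences, which are not independent replicates. Both use the same 3 control libraries, which gives such values without any effect. In 100 draws of unchanged groups with each group's own spread, the covariance averaged 0.291 (range 0.215 to 0.356) and r averaged 0.432. With the spread pooled over the 3 groups the covariance averaged 0.363 (range 0.281 to 0.423). The observed covariance lay above the first mean by 0.0277 and on the other side of the second, inside both ranges. With 3 control libraries they could not be split, so part of any excess may come from the shared controls. No calls were available to overlap. At unadjusted p under 0.05, 11 sequences, miR-451a among them, moved the same way in both. Draws gave 32.8 (range 17 to 44) and 19.3 (range 10 to 30) on average and independent lists 0.874. The 11 lay under the whole first range, so draws with each group's own spread did not reproduce these data in this count.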

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

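The tests below of cell dilution, depth, the GC trend removed, human RNA, a mouse response and LPS were chosen after the results were seen, and the GC correlation and the splits before. In 8 of 129 named sequences all 3 libraries at 1 µM lay on one side of the control mean and all 3 at 10 µM on the other, with means taken on the log2 scale. Some of the 129 were named for a small p in this difference, so the count has no chance value. The log2 difference of 10 from 1 µM was -0.82 for miR-21a-3p, 1.47 for miR-19a-3p, 1.10 for miR-195a-3p, 0.29 for miR-210-5p, 0.26 for miR-200c-3p, 2.72 for miR-146a-3p, -0.65 for miR-331-3p and 3.61 for PC-5p-64858_21. limma's test of that difference passed for none (Benjamini-Hochberg adjusted p = 0.683 each), and the pattern itself was not tested. miR-146a-3p and PC-5p-64858_21 had values under 20 normalized counts in each library.

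Library 3 of the 10 µM group stood apart from the other 8: of 414 abundant sequences, 32 lay over 2-fold above and 18 over 2-fold below every other library. The tables argue against depth, since the control library of like depth had a median r of 0.988 with the others. The correlation with GC content, r = 0.146, lay between the limits set beforehand and does not decide, while library 1 of that group had -0.451 without standing apart. A linear GC trend as the whole cause is argued against. With it removed 41 sequences stood apart where 50 had before, against at most 4 in another library. GC content as a part of the cause stays open, with a slope of 0.151 on the log2 scale per 10% GC in library 3 and -0.161 in library 1. Dilution by cells without the myeloid miRNAs is argued against as the whole cause of the lower miR-146a-5p (log2 ratio -1.68 to the other 8), since 12 other abundant myeloid members had a median of -0.510 (SD 0.87) and a lowest of -1.07, with miR-142a-3p at 1191 the highest of the 9 libraries, miR-223-3p at 802, and miR-155-5p at 33780 and miR-142a-5p at 2811 the lowest of the 9. The highest log2 ratio of the 12, 2.165, was that of miR-451a, which is also in the liver, serum and red cell list. It does not count against dilution, and it widens the SD. Smaller amounts of RNA from other cells stay open, as the fibroblast and muscle list, led by miR-214-3p (2654), took 0.0986% (at most 0.0178% elsewhere) and the liver, serum and red cell list 0.0128% (at most 0.00687% elsewhere), while the epithelial share of 0.0532% lay within the range of the others and the neuronal share of 0.0308%, with miR-128-3p at 2049.6, was the lowest of the 9, and so do a response of that culture and the cell line label, which the sample's title contradicts.

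Library 2 of the 10 µM group held human-named sequences without a mouse hairpin at a sum of 4657, against 1573 in library 3 and 509.6 to 743 elsewhere. Of this class 29 sequences, such as hsa-miR-1307-5p at 261, were above 0 there and listed at 0 in the 7 libraries other than library 3, which held 4 of them, against 0 to 3 such sequences for each of those 7. A response to 10 µM GRd was not excluded, since library 1 of the group had 0.687 times the highest sum of the other groups and library 3 2.12 times. The largest part of the sum in library 2 was hsa-miR-1246_L-1R+2, at 2394, which stood at 376 in library 3 and 13.3 to 39.0 elsewhere. As this sequence was above 0 in all 9 libraries, the sums do not measure human RNA alone. Human RNA in the library is a candidate explanation: the human forms of miR-345-5p and miR-339-3p appeared at 77.4 and 35.9 while the 2 mouse forms, with a mean log2 ratio of -0.03717 to the other libraries, went opposite ways, miR-345-5p at 715 and miR-339-3p at 2819.6, the highest of the 9 beside 2819.1 in control library 3, where its human form was listed at 0. The human form of miR-345-5p also stood at 12.4 in library 3 of the group, where its mouse form, at 632, was the lowest of the 9. No human reference was used here, so the origin remains a hypothesis.

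LPS-induced miRNAs did not separate control from GRd libraries. A net 2-fold rise of this list at 1 µM is argued against by its median log2 difference of 0.04086 and the upper bound of 0.56 for miR-155-5p. By the labels the GRd libraries had LPS and GRd together, so a rise from LPS that GRd offset would give the same values. The values do not decide which control label is right, since such a rise, or a response that had ended after the incubation, stays open.

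The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For 10 µM against control the real count was 0 and the highest of the other splits 1, and for the other 2 comparisons both were 0. A real count of 0 is reached by every split, so this count decides nothing.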

How the results depend on the processing

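The array weights, repeats, mean of 50, GC, human-named, equal-copy and 2-library settings were chosen after seeing the data. The limma counts of 0 stayed at 0 under each alternative run apart from those given next. Leaving out 1 library gave 0 to 13 for 10 µM against control (13 without library 1 and 1 without library 3 of 10 µM), 0 to 0 for 1 µM against control and 0 to 9 for 10 against 1 µM (9 without library 1 of 10 µM). Array weights gave 4 for 1 µM against control, bta-miR-2478_L-2, hsa-miR-7977_1ss6AG, hsa-miR-4454_L-2 and pal-miR-9226-5p_L-4, all higher. The cause of these shifts was not tested. The covariance of the 2 responses was 1.213 with pseudocount 0.1, 0.04263 with pseudocount 10, 0.1707 with the stricter filter, 0.1304 with a mean of at least 50, 0.4132 with 6 samples per fit, and 0.3090 to 0.5014 with 1 library left out. Of the named miRNAs, 6 values passed the threshold under an alternative and 0 reversed. Of list values, 36 lost and 21 gained a call with the direction kept. Without libraries 2 and 3 of 10 µM, where the lone library is assumed to vary like the other groups, the direction of the camera test turned upward for lists with, against control, median log2 differences of LPS-induced 0.25, LPS-lowered 0.28, myeloid 0.00348, miR-15/16 0.44, miR-30 0.29, epithelial 0.37, and against 1 µM of LPS-induced 0.13, myeloid 0.12, miR-15/16 0.45, miR-29 0.29, miR-30 0.21, epithelial 0.47. Among these the LPS-lowered, miR-30 and epithelial lists against control, and the miR-29, miR-30 and epithelial lists against 1 µM, already had medians above 0 with all libraries while the test pointed down. The direction of camera is relative to all other sequences tested, so it can differ from the sign of a median. Leaving out only library 1 of 10 µM moved lists the other way in camera with the preset correlation. The miR-15/16 list then passed downward against control (median -0.62, camera adjusted p = 0.00250) and against 1 µM (median -0.44, camera adjusted p = 0.00335). The LPS-induced and anti-inflammatory lists did so against control (medians -0.24 and -0.22, camera adjusted p = 0.0225 each). The cause was not tested. A further 304 sign changes occurred between values that passed in neither fit and are not counted as reversals. The replicate block gave 0 in all 3 comparisons and a covariance of 0.3192. The miR-34 list then had an adjusted p of 0.0548 (median 1.04) for 10 µM against control, and the fibroblast list 0.0401 (median 1.25) for 10 against 1 µM. Sample numbers did not pair the libraries: 1 of 9 same-number pairs had a correlation over 0.1, and 0 libraries lay closest to their own number in both other groups. The 2 planned tests for read numbers were not run, since the values are not reads. Depth, an estimated 4933690 reads in the shallowest library, limits sequences near 0.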

Other observations

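miRNAs chosen after their values were seen marked library 3 of the 10 µM group. miR-224-5p stood at 500.0 normalized counts there and was listed at 0 in the other 8 libraries. miR-10b-5p stood at 1364, with at most 27.6 elsewhere, and miR-31-5p at 474, with at most 41.8. miR-146b-5p, a member of the LPS-induced list, lay at 40664, with at least 82131 elsewhere, and miR-22-3p at 28958, with at least 58713.

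Sequences ending in CCA and found in no mouse hairpin, as at the end of mature tRNA, took 1.39 ± 0.262% of the 6 GRd libraries and 0.989 ± 0.0556% of the 3 control libraries (SD), higher in 6 of 6 than in any control. This grouping was chosen after the values were seen. An exact two-sided permutation test gave p = 0.0357 over 84 splits, and 0.179 after Benjamini-Hochberg adjustment over 6 tests, which does not pass. bta-miR-2478_L-2, 1 member of the class, stood at 11736, 11924 and 10950 normalized counts in control, 16276, 16356 and 14487 at 1 µM and 16134, 16698 and 21533 at 10 µM. The authors' filter removes tRNA reads, so these values describe what that filter left.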
